A study of Homo sapiens with 8 samples.

How the data were processed

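The samples were 8 total RNA libraries of RD rhabdomyosarcoma cells, 4 with a scrambled hairpin and 4 with a PROX1 hairpin, made with a kit that keeps strand information, per the labels' protocols. Groups and replicate numbers were taken from the labels. The deposited files hold raw counts per gene, 1 file per library, with 58302 genes each and 0 entries that name no gene. The submitters' processing notes name FastQC, HISAT2, HTSeq and DESeq2 and the build GRCh38 (hg38). Versions, annotation release, the strand setting of the counting and the hairpin sequence were not given in the sources used here, so reads of genes that overlap on opposite strands may be shared. No normalization by the authors was applied to the deposited counts.

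Gene identifiers were matched to GENCODE 29 (58039 of 58302), which supplied symbols, biotypes, coordinates (1-based, GRCh38) and transcript sequences. Libraries held 3747090 to 4865161 counts, with no difference past the threshold between groups (n = 4 per group, exact two-sided permutation p = 0.514). A count of 0 allows up to 3 counts, which is 0.617 to 0.801 CPM depending on the library; such limits cover counting error only. The 12 pairs of libraries within a group were compared by chi-square over genes with at least 20 summed counts, and all differed by more than sampling noise (chi-square over degrees of freedom 1.15 to 2.55), so that none was dropped as a copy. This test cannot show that the libraries are independent biological replicates, as the series design describes them. The biological coefficient of variation of the fit was 6.41%.

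The test, samples, gene lists, named-gene rule and most alternatives were fixed before the data were examined. Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr by group, quasi-likelihood F test, group as the only term) with Benjamini-Hochberg adjustment and a threshold of 0.05. Tested genes numbered 12392. Gene lists were tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01, two-sided, adjusted over the 39 of 44 lists with at least 5 measured members. Members were counted as higher or lower over all tested genes and adjusted over the list alone. Camera was repeated with an estimated correlation and replaced by fry, which asks whether the genes of a list move on balance in 1 direction without comparing them with other genes. PROX1, the slow minus fast difference and shares of counts were tested with exact two-sided permutation of the 8 labels (70 arrangements). Principal components used log2 CPM with a prior count of 2. Medians of list changes, means and tests that differ in sign are given as such.

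Named genes were PROX1, the 12 protein-coding genes with the largest rise and the 12 with the largest fall among called genes of at least 5 CPM without overlap between groups, 24 genes given whether called or not, and for each list up to 4 called members with the largest change at 1 CPM or more and the most abundant uncalled member. Genes that share at least 10% of their exon bases with another gene are given with that share. Some named genes are not reported here. Neighbours of PROX1 within 1 Mb were added after its values were seen.

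Alternatives were RLE and upper-quartile factors, no filter on low counts, at least 1 CPM in 4 libraries, DESeq2 1.42.0, limma voom, the replicate number as a block, each library left out, an adjusted threshold of 0.01, a glmTreat test against 1.5-fold, members shared between lists left out, and 2000 genes in the principal components. Added after seeing the data were removal of mitochondrial and small structural RNA genes, an offset for GC content and exon length (loess, span 0.5), and removal of genes whose 3' UTR holds AGCTGGA or GCTGGAA. The 3' UTR of the longest annotated coding transcript was searched in 10431 protein-coding genes of at least 5 CPM and at least 50 bases of 3' UTR. The log2 change was regressed across genes on the presence of each 7-base sequence, with 3' UTR length, GC content and level as covariates (Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9).

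The pipeline was tested on simulated data with 200 changed genes among 12392. The edgeR test recovered 63.8% of 80 genes at a log2 change of 0.5, 97.5% of 80 at 1 and 100% of 40 at 2, and called 15 of 12192 unchanged genes. Camera called the 1 moved list and 0 of 40 unchanged lists. Simulated genes were drawn independently, so false calls of camera on lists with correlated members were not tested.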

Results

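RNA was sequenced from RD cells, a human rhabdomyosarcoma line (a tumour of the skeletal muscle lineage), that carried either a scrambled short hairpin RNA (control) or a hairpin against PROX1 (shPROX1), a homeobox transcription factor. Each group had 4 libraries, which the series design describes as biological replicates, and PROX1 silencing was stated there as 75%. The series title names PROX1 as a regulator of the stemness and growth of rhabdomyosarcoma, so the comparison asks which transcripts differed once PROX1 was silenced. Counts assigned to genes numbered 4245571, 4055205, 4134308 and 4865161 in the control libraries and 4296296, 4086711, 3747090 and 4301987 in the shPROX1 libraries. Levels are given in CPM (library-scaled counts) as mean ± SD of 4 libraries. Log2 changes are shPROX1 minus control ± the standard error of the edgeR fit, so that negative values are lower after silencing. The text calls a gene risen or fallen where the edgeR quasi-likelihood test passed the Benjamini-Hochberg threshold over all tested genes, and a list where camera did so over the tested lists.

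PROX1 itself (Ensembl gene ENSG00000117707, plus strand of chromosome 1, 213983181 to 214041502, GRCh38) fell from 18.6 ± 2.50 CPM in control to 8.91 ± 1.16 CPM in shPROX1 (log2 change -1.07 ± 0.15, n = 4 per group, edgeR adjusted p = 4.89e-06). The control libraries held 85, 66, 69 and 105 PROX1 counts and the shPROX1 libraries 33, 42, 34 and 35, with no overlap in CPM between the groups (exact two-sided permutation p = 0.0286, the smallest that 70 arrangements allow). The fitted PROX1 level after silencing was 47.6% of control (95% interval 38.6% to 58.9%), a decrease of 41.1% to 61.4%. The upper bound of 61.4% lay below the stated 75%, for which the assay was not given in the sources used here. Among the tested genes within 1 Mb of PROX1, PTPN14 on the opposite strand (chromosome 1, 214348696 to 214552449) rose (log2 change 1.25 ± 0.11), ANGEL2 rose (0.27 ± 0.08) and VASH2 fell (-0.87 ± 0.09), whereas CENPF (-0.10 ± 0.06), RPS6KC1 (0.07 ± 0.06) and SMYD2 (-0.16 ± 0.10) did not pass the test.

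PROX1 silencing went with a broad change of mostly small size. Of 12392 tested genes, 4364 (35.2%) differed between the groups, 2147 higher and 2217 lower in shPROX1, and 3186 of these (73.0%) changed by less than 1.5-fold. Changes of at least 2-fold were found for 192 genes that rose and 161 that fell, among them 30 that rose and 7 that fell at least 4-fold. In 4009 genes (32.4% of those tested, against 2.86% by chance) the 4 shPROX1 libraries did not overlap the 4 control libraries. A test against a 1.5-fold change called 369 genes, and without a filter on low counts 538 genes in place of 353 changed at least 2-fold. On the first principal component of the 500 most variable genes (67.7% of their variance) control libraries lay between -13.9 and -13.1 and shPROX1 libraries between 12.8 and 13.8. The second component (13.2%) set control replicate 1 apart at 13.1, against -6.19 to 3.12 for the other libraries. Spearman correlations between libraries were 0.989 to 0.993 within and 0.973 to 0.978 between groups.

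Among protein-coding genes of at least 5 CPM whose groups did not overlap, the rise of MARCHF4, a membrane-bound ubiquitin ligase (chromosome 2, 216257865 to 216372027), was the largest. MARCHF4 rose 10.2-fold from 1.31 ± 0.553 CPM in control to 13.8 ± 1.88 CPM in shPROX1. The adhesion protein AMIGO2 rose 8.22-fold (log2 change 3.04 ± 0.17), the protease-activated receptor F2RL1 7.24-fold, the membrane-anchored semaphorin SEMA7A 5.88-fold and KITLG, the ligand of the KIT receptor, 5.04-fold. Among more abundant transcripts, the serine protease inhibitor SERPINE2 (59.9 ± 3.81 to 279 ± 8.41 CPM) and the caveolar coat proteins CAV1 (46.6 ± 7.37 to 228 ± 13.3 CPM, log2 change 2.29 ± 0.08) and CAV2 (2.13 ± 0.19) rose as well. COL12A1 (2.27 ± 0.15), a fibril-associated collagen, the tetraspan membrane protein TM4SF18 (2.25 ± 0.18) and the myosin heavy chain MYH15 (2.12 ± 0.12) were also among the 12 largest rises. The largest falls of such genes included ion channel genes: KCNF1, a potassium channel subunit (chromosome 2, 10911937 to 10914225), fell from 15.9 ± 1.07 to 3.65 ± 0.783 CPM (log2 change -2.12 ± 0.18), with the sodium channel SCN7A (-1.84 ± 0.11) and the potassium channel KCNH2 (-1.57 ± 0.18). MFN1, a GTPase of mitochondrial fusion, fell from 113 ± 4.0 to 33.8 ± 2.84 CPM (log2 change -1.74 ± 0.07), and IGFBP5, an insulin-like growth factor binding protein, from 177 ± 21.4 to 53.1 ± 3.29 CPM (-1.74 ± 0.08). The secreted semaphorin SEMA3B (-2.09 ± 0.22), the somatostatin receptor SSTR2 (-1.56 ± 0.18), the metalloprotease ADAM28 (-1.74 ± 0.22), the keratin KRT40 (-1.72 ± 0.17), ABAT, which degrades the transmitter GABA (-1.67 ± 0.10), ARHGAP15 (-1.66 ± 0.22) and NKAIN4 (-1.65 ± 0.17) made up the rest of the 12 largest falls. All of these genes had non-overlapping groups and edgeR adjusted p values of at most 3.21e-06. Some annotated 3' UTRs carried the bases AGCTGGAA, or AGCTGGA or GCTGGAA alone. Carriers were slightly lower after silencing (median log2 changes of -0.11 to -0.04 by type of match) in a search added after the gene changes were seen. The bounds of that search were set before it was run. Of 10431 searched genes, 2731 carried at least 1 of the 7-base sequences, so a match alone does not mark a gene as a target of the hairpin. The 8-base sequence was in SEMA3B, and a 7-base part in MFN1, IGFBP5 and SSTR2 among the falls and in CAV1, SERPINE2 and MYH15 among the rises.

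**Figure D1:**
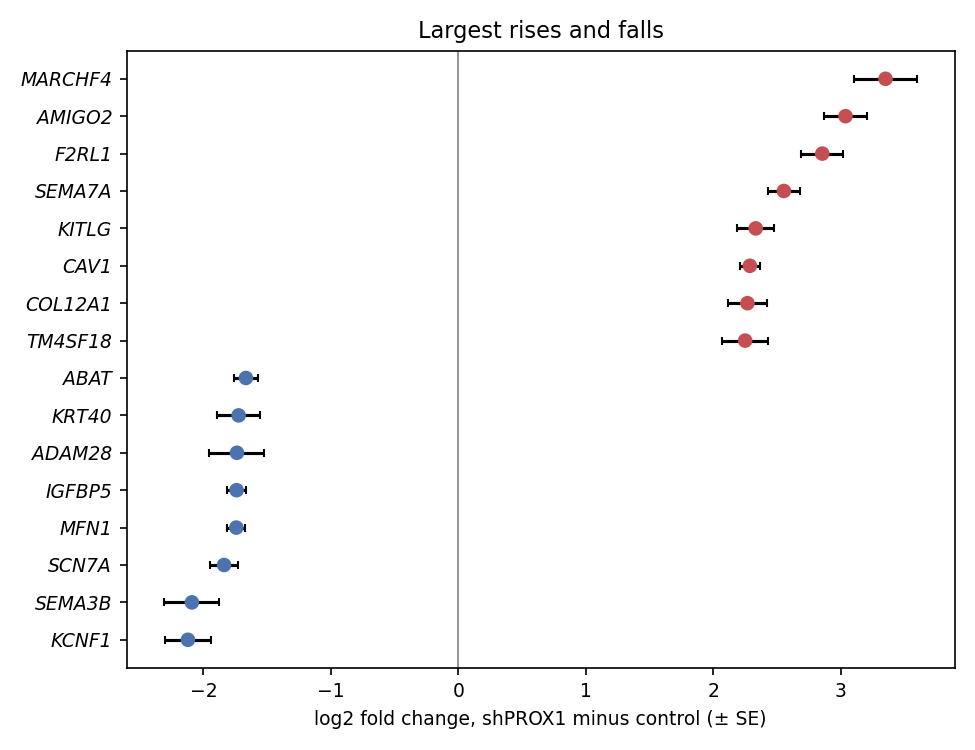
Log2 change (shPROX1 minus control; dots, bars are SE of the edgeR fit, n = 4 libraries per group) of the 8 genes with the largest rise (red) and the 8 with the largest fall (blue) among called protein-coding genes of at least 5 CPM whose groups did not overlap. The rises run from 2.25 for TM4SF18 to 3.35 for MARCHF4 and the falls from -1.67 for ABAT to -2.12 for KCNF1.

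Many contractile genes and several myogenic transcription factor genes were lower after PROX1 silencing, while MYOD1, the myogenic master regulator, was not measurably different. MYOD1 levels were 71.0 ± 7.37 to 73.1 ± 4.35 CPM from control to shPROX1 (log2 change 0.04 ± 0.07, edgeR adjusted p = 0.714). MYOG, which drives terminal differentiation (chromosome 1, 203083132 to 203086036), fell 2.50-fold from 121 ± 5.63 CPM in control to 48.4 ± 2.55 CPM in shPROX1 (log2 change -1.32 ± 0.06, edgeR adjusted p = 1.65e-13). The transcription factors MEF2C (-0.49 ± 0.10), PAX7 (-0.41 ± 0.08), PITX3 (-0.89 ± 0.09) and MSC (-1.09 ± 0.06) also fell. Values for PAX3 (0.14 ± 0.13) and SIX4 (0.05 ± 0.07) did not pass the test. MYF5 had 0 counts, which allows up to 0.801 CPM in the shallowest library. Myogenic transcription factors counted 0 higher and 9 lower among 20 measured (0 and 10 adjusted over the list alone). The myogenic factor list had a median log2 change of -0.20 and a camera adjusted p = 0.00169, and adjusted p = 0.108 with an estimated correlation. Contractile genes fell too. Sarcomere and contractile genes counted 2 higher and 26 lower among 38 measured (3 and 27 adjusted over the list alone). The sarcomere list had a median log2 change of -0.56 and a camera adjusted p = 6.73e-08, and adjusted p = 0.0692 with an estimated correlation. The embryonic myosin heavy chain MYH3 fell from 156 ± 12 to 81.6 ± 2.36 CPM (log2 change -0.94 ± 0.06). The perinatal form MYH8 (-1.22 ± 0.19), muscle creatine kinase CKM (-1.11 ± 0.14) and the myosin chaperone UNC45B (-1.05 ± 0.10) fell too. Desmin, an intermediate filament of muscle, fell by less, from 544 ± 19.1 to 479 ± 19.9 CPM (DES, -0.18 ± 0.04). The Z-disc protein gene MYPN (1.04 ± 0.11) rose, and TPM2 (0.08 ± 0.05) did not pass the test. The 8-base sequence was annotated in the 3' UTR of UNC45B, and a 7-base part in MEF2C, PAX7, CKM and MYPN. MSC shared 19.6% of its exon bases with its antisense neighbour MSC-AS1.

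Both fibre-type lists fell. Slow-fibre genes counted 1 higher and 7 lower among 8 measured (1 and 7 adjusted over the list alone). The slow-fibre list had a median log2 change of -0.69 and a camera adjusted p = 6.44e-04, and adjusted p = 0.141 with an estimated correlation. The slow troponin genes TNNI1 (-1.0 ± 0.06) and TNNC1 (-0.75 ± 0.18) fell, with MYH7B (-0.78 ± 0.18) and TPM3 (-0.69 ± 0.04). Fast-fibre genes counted 0 higher and 5 lower among 7 measured (0 and 5 adjusted over the list alone). The fast-fibre list had a median log2 change of -0.76 and a camera adjusted p = 2.08e-04, and adjusted p = 0.0692 with an estimated correlation. The calcium pump of fast muscle ATP2A1 (-1.27 ± 0.11), the fast myosin light chains MYL11 (-0.81 ± 0.06) and MYL1 (-0.76 ± 0.06) and MYH8 fell. MYH2 (-0.10 ± 0.26) did not pass the test. The mean of 8 slow genes was 6.57 ± 0.0740 log2 CPM in control and 6.04 ± 0.0597 in shPROX1. That of 7 fast genes was 4.49 ± 0.0916 and 3.78 ± 0.0260. The slow minus fast difference was 2.08 ± 0.125 in control and 2.26 ± 0.0569 in shPROX1 (n = 4 per group), a shift of 0.185 that did not pass an exact two-sided permutation test (p = 0.0571). With 1 CPM required in 4 libraries the shift was 0.220 (exact p = 0.0286) and without control replicate 4 it was 0.223 (exact p = 0.0286). It was 0.0773 without control replicate 2 (exact p = 0.286) and 0.0340 without MYH7B, MYL6B, TPM3 and ATP2A2, which are expressed outside slow muscle (exact p = 0.743). Excitation-contraction coupling genes counted 2 higher and 11 lower among 20 measured (3 and 11 adjusted over the list alone). The coupling list had a median log2 change of -0.29 and a camera adjusted p = 0.0159, and adjusted p = 0.185 with an estimated correlation. The calcium channel CACNA1S (-0.95 ± 0.22), its partner STAC3 (-0.70 ± 0.09) and the calcium pump regulator MRLN (-0.74 ± 0.19) fell. The acetylcholine receptor subunit CHRNA1 (0.01 ± 0.04) did not pass. Fusion and surface genes of myoblasts went both ways. This group counted 6 higher and 7 lower among 16 measured (6 and 7 adjusted over the list alone). The fusion list did not pass (median -0.13, camera adjusted p = 0.844). The myomaker gene MYMK (-1.31 ± 0.31) and the receptor ERBB3 (-1.13 ± 0.12) fell. Myostatin, an inhibitor of muscle growth, fell from 1352 ± 69.6 to 654 ± 24.8 CPM (MSTN, -1.05 ± 0.04). The proteoglycan gene SDC4 rose 3.59-fold, and JAM3 (-0.08 ± 0.05) did not pass. AGCTGGAA was annotated in the 3' UTR of STAC3, and a 7-base part in TPM3, MYL1, SDC4 and JAM3.

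**Figure D2:**
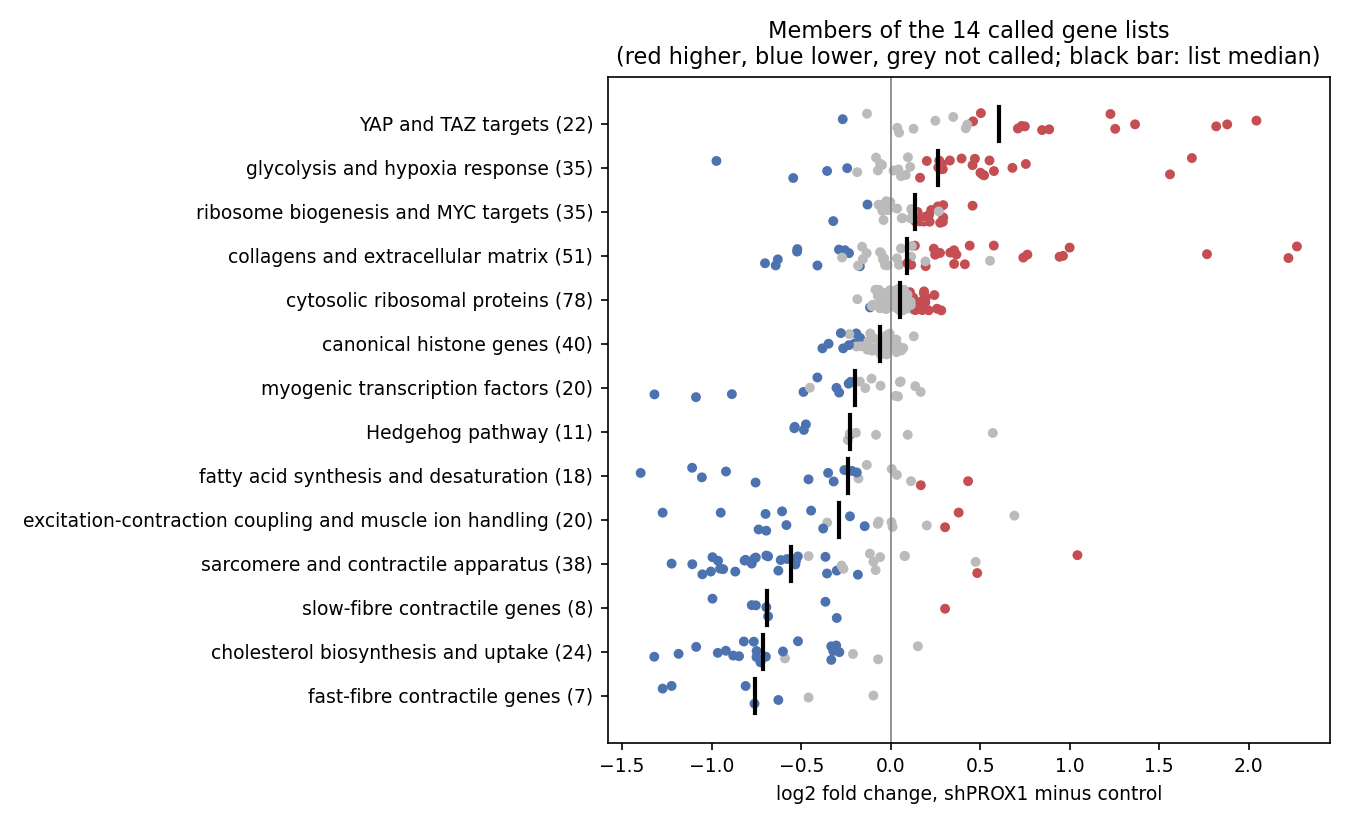
Log2 change (shPROX1 minus control) of each measured member, 1 dot per gene, of the 14 lists called by camera, with the number of members in brackets, called members in red (higher) or blue (lower), others in grey, and the list median as a black bar. Medians run from -0.76 for fast-fibre contractile genes to 0.61 for YAP and TAZ targets.

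Lipid synthesis genes fell after silencing. Cholesterol biosynthesis and uptake genes counted 0 higher and 20 lower among 24 measured (0 and 20 adjusted over the list alone). The cholesterol list had a median log2 change of -0.71 and a camera adjusted p = 2.96e-16, and adjusted p = 0.0177 with an estimated correlation. Of the 14 called lists, this was the 1 that kept its call with an estimated correlation. INSIG1, a sterol sensor of the endoplasmic reticulum, fell 2.50-fold from 79.1 ± 3.17 CPM in control to 31.7 ± 2.42 CPM in shPROX1. HMGCS1, an early enzyme of the mevalonate pathway, fell from 163 ± 9.37 to 71.6 ± 3.45 CPM (log2 change -1.18 ± 0.06). Squalene epoxidase SQLE (-0.97 ± 0.06) fell as well, while the lipid carrier STARD4 (-0.07 ± 0.06) did not pass. Fatty acid synthesis and desaturation genes counted 2 higher and 11 lower among 18 measured (2 and 11 adjusted over the list alone). The fatty acid list had a median log2 change of -0.24 and a camera adjusted p = 8.00e-04, and adjusted p = 0.206 with an estimated correlation. The desaturase SCD fell from 798 ± 27.9 to 384 ± 10.8 CPM (log2 change -1.05 ± 0.04). The desaturases FADS1 (-1.11 ± 0.06) and FADS2 (-1.40 ± 0.19) and the triglyceride enzyme DGAT2 (-0.92 ± 0.22) fell, and the elongase ELOVL5 (0.01 ± 0.06) did not pass. The 3' UTRs of SCD and FADS1 carried a 7-base part of AGCTGGAA.

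Targets of YAP and TAZ, the effectors of the Hippo pathway, rose. YAP and TAZ targets counted 13 higher and 1 lower among 22 measured (15 and 1 adjusted over the list alone). The YAP and TAZ list had a median log2 change of 0.61 and a camera adjusted p = 4.44e-08, and adjusted p = 0.108 with an estimated correlation. NT5E, a surface nucleotidase, rose 4.12-fold from 20.3 ± 3.18 CPM in control to 84.0 ± 3.33 CPM in shPROX1, and the receptor kinase AXL rose 3.68-fold. The matricellular genes CCN2 (1.82 ± 0.21) and CCN1 (1.36 ± 0.20) rose as well, while AMOTL1 (0.05 ± 0.05) did not pass. Collagen and matrix genes moved both ways with more rises. Matrix genes counted 22 higher and 10 lower among 51 measured (23 and 10 adjusted over the list alone). The matrix list had a median log2 change of 0.09 and a camera adjusted p = 0.0316, and adjusted p = 0.302 with an estimated correlation. COL12A1 rose, as given above. The collagen cross-linking enzyme LOX (1.77 ± 0.20) and COL7A1 (1.0 ± 0.08) rose, and COL5A2 (-0.04 ± 0.03) did not pass. The matrix list lost its camera call without control replicate 2 (adjusted p = 0.0580), without shPROX1 replicate 4 (adjusted p = 0.0722) and without genes that carry a 7-base match (adjusted p = 0.121). Stemness and pluripotency genes counted 12 higher and 7 lower among 24 measured (13 and 8 adjusted over the list alone). The stemness list did not pass (median 0.28, camera adjusted p = 0.0844). Without a filter on low counts (camera adjusted p = 0.0380) or without genes that carry a 7-base match (camera adjusted p = 0.0195) it was called. At an estimated correlation camera gave adjusted p = 0.333 for all members and adjusted p = 0.293 without genes that carry a match. The inhibitor of differentiation ID1 rose from 48.7 ± 6.54 to 98.1 ± 2.56 CPM, with its relative ID2 (1.44 ± 0.17) and the transcription factor SOX9 (1.30 ± 0.27). MYC fell from 229.6 ± 9.56 to 177 ± 6.53 CPM (log2 change -0.38 ± 0.05), and ZEB1 (-0.15 ± 0.09) did not pass. MYCN, with 46 counts over the control and 13 over the shPROX1 libraries, was below the filter. Immediate early genes counted 10 higher and 4 lower among 21 measured (11 and 4 adjusted over the list alone). The immediate early list did not pass (median 0.26, camera adjusted p = 0.0723). It was called with the replicate number as a block (camera adjusted p = 0.0452), without shPROX1 replicate 1 (camera adjusted p = 0.0343), without members of other lists (camera adjusted p = 0.0114) and without genes that carry a 7-base match (camera adjusted p = 0.0134). Its camera adjusted p at an estimated correlation was 0.388 for all members and 0.279 without genes that carry a match. The immediate early genes included rises of FOSL1 (1.47 ± 0.20) and ARC (1.16 ± 0.27) and a fall of JUND (-1.19 ± 0.10), with KLF4 (0.38 ± 0.15) not called. A 7-base match was annotated in the 3' UTRs of NT5E, LOX, AMOTL1 and JUND.

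Genes of glycolysis and the hypoxia response rose as a list. Glycolysis and hypoxia genes counted 20 higher and 4 lower among 35 measured (20 and 4 adjusted over the list alone). The glycolysis list had a median log2 change of 0.27 and a camera adjusted p = 4.27e-06, and adjusted p = 0.206 with an estimated correlation. The peptide hormone gene ADM rose 2.95-fold from 69.0 ± 2.61 CPM in control to 204 ± 9.49 CPM in shPROX1. ANGPTL4 (1.68 ± 0.25) and the angiogenic factor VEGFA (0.75 ± 0.13) rose. DDIT4, an inhibitor of mTOR signalling, fell (-0.97 ± 0.08), and the glycolytic enzyme GPI (0.08 ± 0.05) did not pass. Ribosome biogenesis genes and MYC targets counted 17 higher and 2 lower among 35 measured (17 and 2 adjusted over the list alone). The ribosome biogenesis list had a median log2 change of 0.14 and a camera adjusted p = 0.0121, and adjusted p = 0.297 with an estimated correlation. The polyamine enzyme SRM (0.46 ± 0.11), TCOF1 (0.29 ± 0.06) and MRTO4 (0.29 ± 0.06) rose, RRP1B (-0.32 ± 0.05) fell and NPM1 (0.04 ± 0.04) did not pass. Cytosolic ribosomal proteins counted 18 higher and 1 lower among 78 measured (16 and 1 adjusted over the list alone). The ribosomal protein list had a median log2 change of 0.05 and a camera adjusted p = 0.0123, and adjusted p = 0.646 with an estimated correlation. RPS26 (0.28 ± 0.05), RPS16 (0.26 ± 0.06), RPL38 (0.24 ± 0.06) and FAU (0.21 ± 0.06) rose by small amounts, and RPS18 (0.04 ± 0.05) was not called. This camera call ended without control replicate 2 (adjusted p = 0.123) or 4 (adjusted p = 0.0580), without genes that carry a 7-base match (adjusted p = 0.0994) and by fry (adjusted p = 0.239). Canonical histone genes counted 0 higher and 8 lower among 40 measured (0 and 8 adjusted over the list alone). The histone list had a median log2 change of -0.06 and a camera adjusted p = 0.0278, and adjusted p = 0.559 with an estimated correlation. H1-1 (-0.38 ± 0.08), H4C1 (-0.35 ± 0.08), H3C1 (-0.28 ± 0.05) and H2AC6 (-0.27 ± 0.06) fell, and HIST1H3B (-0.02 ± 0.04) was not called. The histone camera call ended without control replicate 1 (adjusted p = 0.190), without shPROX1 replicate 1 (adjusted p = 0.0578) and by fry (adjusted p = 0.105). The 3' UTR of FAU held the 8-base sequence and those of DDIT4, GPI, RRP1B and H2AC6 a 7-base part. FAU also shared 21.6% of its exon bases with SYVN1.

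Receptor and ligand genes of several pathways differed. FGFR4, a fibroblast growth factor receptor of myogenic cells (chromosome 5, 177086886 to 177098144), fell 2.23-fold from 158 ± 9.50 CPM in control to 70.8 ± 10.4 CPM in shPROX1 (log2 change -1.15 ± 0.08, edgeR adjusted p = 5.07e-11). FGFR1 (-0.18 ± 0.05) fell slightly, and FGFR3 was low and not measurably different (4.35 ± 2.52 to 4.31 ± 1.32 CPM). The growth factor genes FGF1 (0.83 ± 0.18) and FGF2 (0.66 ± 0.07) and the phosphatase gene DUSP5 (3.41-fold) rose, and DUSP4 (-0.03 ± 0.05) did not pass. Fibroblast growth factor genes counted 5 higher and 6 lower among 25 measured (6 and 7 adjusted over the list alone). The fibroblast growth factor list did not pass (median 0.00, camera adjusted p = 0.998). Its mean was 0.04 and the tested direction up. Notch pathway genes counted 2 higher and 9 lower among 23 measured (2 and 9 adjusted over the list alone). The Notch list did not pass (median -0.17, camera adjusted p = 0.0727). The Notch call was gained without a filter on low counts (camera adjusted p = 0.0274). The receptor NOTCH3 fell from 124 ± 7.16 to 69.7 ± 7.98 CPM (log2 change -0.83 ± 0.07), with the target gene HEY1 (-0.64 ± 0.05), HES6 (-1.41 ± 0.15) and the glycosyltransferase LFNG (-0.74 ± 0.11). The ligand JAG1 rose 2.61-fold, and NOTCH1 (0.08 ± 0.06) and HES1 (-0.02 ± 0.25) did not pass. Insulin-like growth factor genes counted 7 higher and 5 lower among 18 measured (7 and 6 adjusted over the list alone). The insulin-like growth factor list did not pass (median -0.05, camera adjusted p = 0.641). IGF2 fell from 206 ± 12 to 107 ± 16.8 CPM (log2 change -0.96 ± 0.08), as did IGFBP5. The binding protein protease PAPPA (1.87 ± 0.27) and the adaptor IRS2 (1.12 ± 0.22) rose, and IGF2BP1 (-0.17 ± 0.07) did not pass. Hedgehog pathway genes counted 0 higher and 5 lower among 11 measured (0 and 5 adjusted over the list alone). The Hedgehog list had a median log2 change of -0.23 and a camera adjusted p = 0.0123, and adjusted p = 0.206 with an estimated correlation. The transcription factor GLI3 (-0.54 ± 0.12) and the surface coreceptors GAS1 (-0.54 ± 0.05), BOC (-0.49 ± 0.06) and CDON (-0.47 ± 0.05) fell. FOXM1 (0.09 ± 0.09), which shared 15.9% of its exon bases with ITFG2 on the opposite strand, did not pass. Wnt targets and modulators counted 6 higher and 9 lower among 22 measured (6 and 11 adjusted over the list alone). The Wnt list did not pass (median -0.18, camera adjusted p = 0.294). The ligand WNT11 (-2.36 ± 0.37) and the inhibitor NKD2 (-0.87 ± 0.30) fell, the NKD2 call ending with DESeq2 (adjusted p = 0.129) and in several fits with 1 library left out. The inhibitor DKK1 rose from 209.9 ± 12.7 to 413 ± 21.5 CPM, the receptor FZD1 (0.88 ± 0.08) rose, and WNT5A (-0.02 ± 0.06) did not pass. FGFR4, JAG1 and IRS2 carried AGCTGGAA in the 3' UTR, and FGFR1, FGF2, NOTCH3, IGFBP5, PAPPA, IGF2BP1 and FZD1 a 7-base part. FGF2 shared 11.9% of its exon bases with NUDT6.

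**Figure D3:**
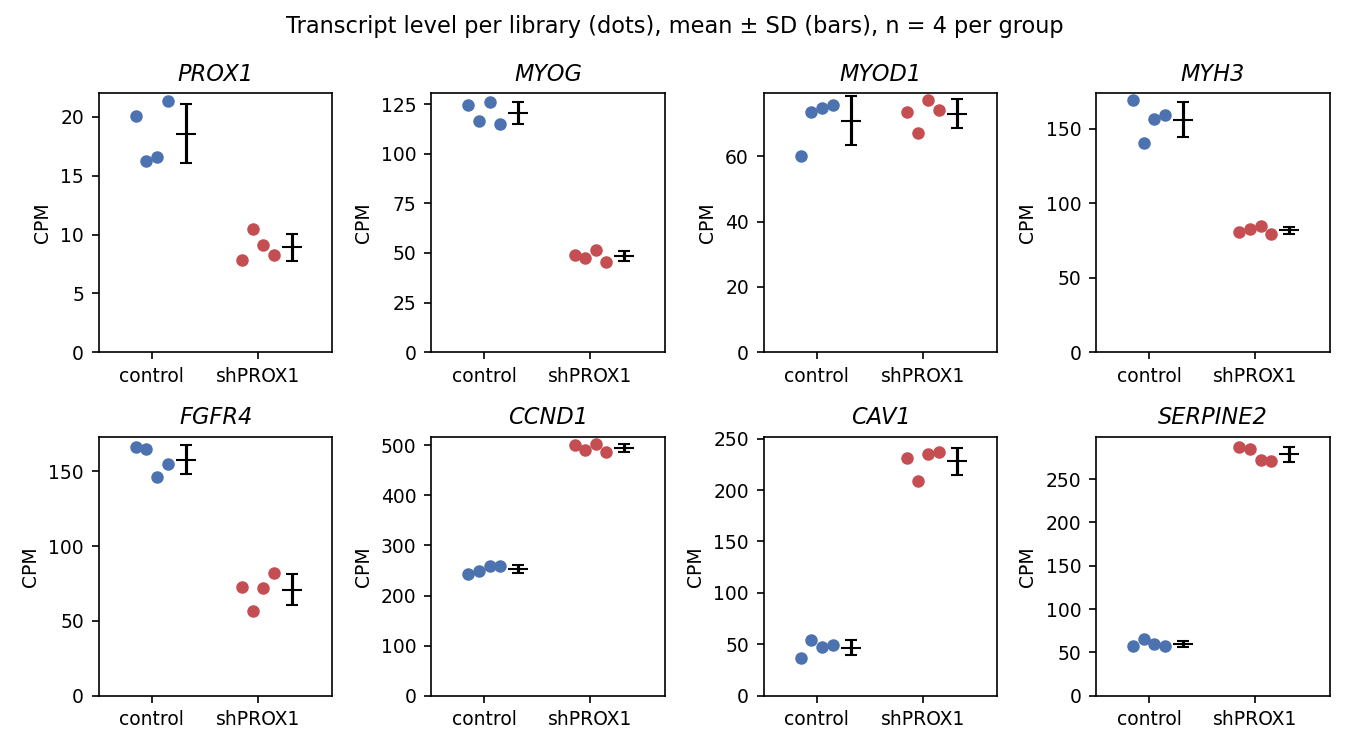
CPM of PROX1, MYOG, MYOD1, MYH3, FGFR4, CCND1, CAV1 and SERPINE2 in each library (dots; control blue, shPROX1 red) with mean ± SD beside them (n = 4 per group), on axes that start at 0. The groups do not overlap for any gene shown except MYOD1, where control replicate 1 is the lowest library.

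Cell cycle genes moved both ways, mostly by small amounts. The cyclin gene CCND1 rose from 252 ± 7.97 CPM in control to 496 ± 8.0 CPM in shPROX1 (log2 change 0.97 ± 0.05) and CCND2 from 1154 ± 36.5 to 1419.8 ± 17.2 CPM (0.30 ± 0.03). The cyclin-dependent kinase inhibitor gene CDKN1A rose from 80.5 ± 5.10 to 126 ± 7.60 CPM (0.64 ± 0.06), while CDKN1C (-1.21 ± 0.31) fell. The proliferation marker MKI67 did not pass (209.8 ± 37.8 to 235 ± 52.4 CPM, 0.16 ± 0.12). Cyclin-dependent kinase inhibitors and G1 regulators counted 7 higher and 6 lower among 20 measured (7 and 6 adjusted over the list alone). The G1 list did not pass (median 0.12, camera adjusted p = 0.247). They included an uncalled CDK4 (-0.08 ± 0.05) and a fall of BTG2 (-0.63 ± 0.23). The BTG2 call ended with DESeq2 (adjusted p = 0.147), without a filter on low counts and in several fits with 1 library left out. S phase genes counted 11 higher and 5 lower among 45 measured (13 and 5 adjusted over the list alone). The S phase list did not pass (median 0.06, camera adjusted p = 0.252). TK1 (0.33 ± 0.06), RRM2 (0.31 ± 0.06) and UHRF1 (0.29 ± 0.04) rose, E2F2 (-0.64 ± 0.07) fell and MCM7 (0.01 ± 0.04) did not pass. Genes of the G2 and M phases counted 14 higher and 6 lower among 48 measured (14 and 7 adjusted over the list alone). The G2 and M phase list did not pass (median 0.06, camera adjusted p = 0.176). ANLN (0.40 ± 0.04) and KIF20A (0.26 ± 0.05) rose, ECT2 (-0.48 ± 0.07) and SMC2 (-0.45 ± 0.05) fell and TOP2A (-0.07 ± 0.04) did not pass. Targets of p53 counted 8 higher and 7 lower among 26 measured (8 and 9 adjusted over the list alone). The p53 list did not pass (median -0.06, camera adjusted p = 0.734). TP53INP1 (-1.20 ± 0.20), FDXR (-1.10 ± 0.20) and SESN1 (-1.06 ± 0.15) fell, GADD45A (0.65 ± 0.10) rose and MDM2 (-0.05 ± 0.05) did not pass. Without a filter on low counts the G1 (camera adjusted p = 0.0240), S phase (camera adjusted p = 0.0380) and G2 and M phase lists (camera adjusted p = 0.0190) were called. Cell death regulators counted 6 higher and 3 lower among 26 measured (7 and 3 adjusted over the list alone). The cell death list did not pass (median 0.02, camera adjusted p = 0.376). PMAIP1 (0.71 ± 0.06) and the inflammatory caspase CASP4 (0.34 ± 0.10) rose, CASP9 (-0.61 ± 0.13) fell and TNFRSF10B (-0.08 ± 0.05) did not pass. The CASP4 call ended without shPROX1 replicate 1 (edgeR adjusted p = 0.0542). The 8-base sequence lay in the 3' UTRs of E2F2, ECT2, SESN1 and MDM2 and a 7-base part in that of BTG2. CDK4 shared 43.2% of its exon bases with TSPAN31 and CCND1 10.3% with LTO1, each on the opposite strand.

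Stress, immune and respiratory lists were not called by camera in the main comparison. Unfolded protein response and ATF4 targets counted 12 higher and 5 lower among 32 measured (14 and 5 adjusted over the list alone). The unfolded protein list did not pass (median 0.11, camera adjusted p = 0.0723). It was gained by leaving out members of other lists (camera adjusted p = 0.0145) and without a filter on low counts (camera adjusted p = 0.0103). EDEM1 (0.63 ± 0.10) and SDF2L1 (0.57 ± 0.10) rose, TRIB3 (-0.64 ± 0.17) and DDIT4 fell and PDIA6 (0.12 ± 0.05) did not pass. Interferon-stimulated genes counted 9 higher and 12 lower among 40 measured (9 and 12 adjusted over the list alone). The interferon list did not pass (median -0.12, camera adjusted p = 0.459). The immunoproteasome subunit PSMB9 (-0.88 ± 0.21), DDX60 (-0.82 ± 0.11) and BST2 (-0.82 ± 0.24) fell, and IFI44 (-0.01 ± 0.05) did not pass. MX2 (0.75 ± 0.23) rose, a call that ended with DESeq2 (adjusted p = 0.0772), without control replicate 1 and without shPROX1 replicate 3. Inflammatory genes counted 4 higher and 2 lower among 12 measured (4 and 2 adjusted over the list alone). The inflammatory list did not pass (median 0.22, camera adjusted p = 0.398). The cytokines LIF (1.10 ± 0.20) and CCL2 (0.29 ± 0.11) rose, CCL5 (-0.89 ± 0.17) and CXCL8 (-0.56 ± 0.17) fell and NFKB2 (-0.11 ± 0.10) did not pass. The CCL2 call ended with DESeq2 (adjusted p = 0.161), limma voom, upper-quartile factors, no filter on low counts and the replicate block. It also ended with the GC and length offset, without carriers of a 7-base match and in most fits with 1 library left out. That of CXCL8 ended without shPROX1 replicate 4 (edgeR adjusted p = 0.0582). Nuclear-encoded respiratory chain genes counted 5 higher and 3 lower among 53 measured (2 and 3 adjusted over the list alone). The respiratory chain list did not pass (median -0.01, camera adjusted p = 0.97). Its tested direction was up. NDUFS1 (-0.35 ± 0.04) and NDUFB5 (-0.37 ± 0.06) fell, NDUFA10 (0.20 ± 0.05) rose and ATP5F1B (0.05 ± 0.04) did not pass. NDUFS3 (0.19 ± 0.08) rose, a call that ended with DESeq2 (adjusted p = 0.130), upper-quartile factors and the replicate block. It also ended without carriers of a 7-base match and in most fits with 1 library left out. Genes of muscle wasting counted 2 higher and 1 lower among 14 measured (2 and 0 adjusted over the list alone). The muscle wasting list did not pass (median 0.05, camera adjusted p = 0.385). The lysosomal protease CTSL rose from 74.2 ± 4.54 to 129 ± 5.65 CPM, the autophagy receptor SQSTM1 (0.55 ± 0.05) rose, and FBXO21 (0.04 ± 0.05) did not pass. FOXO4 (-0.28 ± 0.11) fell, a call that ended with DESeq2 (adjusted p = 0.176), RLE factors, either other filter and the replicate block. It also ended in most fits with 1 library left out. PROX1 binding partners and nuclear receptor axis genes counted 4 higher and 4 lower among 14 measured (4 and 4 adjusted over the list alone). The PROX1 partner and nuclear receptor list did not pass (median 0.11, camera adjusted p = 0.521). The nuclear receptor NR2F1 (0.81 ± 0.08) rose, ESRRA (-0.60 ± 0.10) and the demethylase KDM1A (-0.27 ± 0.05) fell, and NCOR1 (0.06 ± 0.06) did not pass. CXCL8 and NDUFS1 carried the 8-base sequence in the 3' UTR and DDIT4, EDEM1, NDUFB5, SQSTM1 and FOXO4 a 7-base part. SQSTM1 shared 20.7% of its exon bases with MRNIP and NDUFS3 19.6% with PTPMT1.

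Among the lists tested in the main comparison, markers of other cell types did not pass by camera, except for smooth muscle in 1 alternative. Lymphatic endothelial markers counted 3 higher and 1 lower among 8 measured (3 and 2 adjusted over the list alone). The lymphatic list did not pass (median 0.12, camera adjusted p = 0.121). NR2F1, the semaphorin receptor NRP2 (0.62 ± 0.06) and ANGPT2 (0.49 ± 0.05) rose, ITGA9 (-0.26 ± 0.07) fell and NR2F2 (-0.01 ± 0.13) did not pass. Blood endothelial markers counted 1 higher and 0 lower among 5 measured (1 and 0 adjusted over the list alone). The blood endothelial list did not pass (median -0.07, camera adjusted p = 0.724). Its tested direction was up. FLT1 (0.46 ± 0.08) rose and TEK (-0.07 ± 0.09) did not pass. Fibroblast markers counted 4 higher and 2 lower among 7 measured (4 and 2 adjusted over the list alone). The fibroblast list did not pass (median 0.24, camera adjusted p = 0.385). Vimentin rose from 1188 ± 34.5 to 1964 ± 19 CPM (VIM, 0.73 ± 0.03), THY1 (0.46 ± 0.07) and PDGFRB (0.68 ± 0.21) rose, FBLN1 (-0.52 ± 0.08) fell and S100A4 (0.03 ± 0.13) did not pass. The PDGFRB call ended without shPROX1 replicate 1 (edgeR adjusted p = 0.0553) or 4 (edgeR adjusted p = 0.0574). Smooth muscle and myofibroblast markers counted 3 higher and 2 lower among 11 measured (3 and 2 adjusted over the list alone). The smooth muscle list did not pass (median 0.12, camera adjusted p = 0.395). Without members of other lists it was called (camera adjusted p = 0.0471), and its median on voom values was 0.38 in place of 0.14. TAGLN (1.24 ± 0.17), SMTN (0.38 ± 0.11) and SYNPO2 (0.38 ± 0.06) rose. Neuronal markers counted 1 higher and 3 lower among 9 measured (1 and 4 adjusted over the list alone). The neuronal list did not pass (median -0.27, camera adjusted p = 0.248). The neurofilament genes NEFM (-0.95 ± 0.13) and NEFL (-0.41 ± 0.07) and MAP2 (-0.24 ± 0.05) fell, ELAVL2 (0.83 ± 0.11) rose and ISL1 (-0.05 ± 0.14) did not pass. Fry, which does not compare a list with other genes, called the lymphatic, fibroblast, smooth muscle and neuronal lists (adjusted p = 6.84e-04, 0.00169, 0.0375 and 0.00445). Fry also called the G1, Notch, insulin-like growth factor, stemness, unfolded protein, inflammatory, immediate early, cell death and muscle wasting lists, each at an adjusted p of at most 0.0161. Lists with under 5 measured members were counted and not tested in the main comparison. The run without a filter on low counts also tested lists that reached 5 members only there, and its calls of those are not given. Schwann cell and neural crest markers counted 1 higher and 2 lower among 4 measured (1 and 2 adjusted over the list alone). MBP (-1.17 ± 0.19) and ERBB3 fell, NGFR (0.42 ± 0.05) rose and PMP22 (-0.06 ± 0.09) did not pass. Epithelial markers counted 2 higher and 0 lower among 4 measured (2 and 0 adjusted over the list alone). KRT18 (0.47 ± 0.06) and CLDN4 (0.76 ± 0.22) rose and KRT8 (0.31 ± 0.17) did not pass. Adipocyte markers counted 1 higher and 0 lower among 3 measured (1 and 0 adjusted over the list alone). PNPLA2 (0.55 ± 0.21) rose and CEBPA (-0.14 ± 0.15) did not pass. The PNPLA2 call ended with DESeq2 (adjusted p = 0.0958), limma voom, the replicate block, without carriers of a 7-base match and in most fits with 1 library left out. Of the leukocyte markers 1 was measured and not called, and of the hepatocyte and bile acid genes 0 passed the filter. A 7-base match was annotated in NRP2, ITGA9, FLT1, THY1, NEFL, MBP and KRT8. Exon overlap with a neighbour reached 16.3% for KRT18 (with KRT8 on the opposite strand), 12.4% for VIM (VIM-AS1) and 11.4% for TAGLN (PCSK7).

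Of 13 mitochondrially encoded protein genes, 10 fell, while neither their list nor the mitochondrial share of counts passed its test. The mitochondrial share of counts was 0.0980%, 0.702%, 0.473% and 0.681% in the control libraries and 0.157%, 0.127%, 0.278% and 0.120% in the shPROX1 libraries. The means were 0.489% ± 0.280 and 0.171% ± 0.0735 (n = 4 per group, exact two-sided permutation p = 0.143). Without control replicate 1, the lowest control, the control libraries lay at 0.473% to 0.702%. The exact permutation p was then 0.0286, the smallest that 35 arrangements allow. With any other library left out the exact permutation p was 0.143 to 0.257. Mitochondrially encoded protein genes counted 0 higher and 10 lower among 13 measured (0 and 12 adjusted over the list alone). The mitochondrial list did not pass (median -1.12, camera adjusted p = 0.0727). MT-ND2 (-1.79 ± 0.52), MT-ATP6 (-1.72 ± 0.52), MT-ND1 (-1.70 ± 0.48) and MT-ND4 (-1.56 ± 0.46) fell, and MT-ND4L (-0.79 ± 0.35) did not pass. With limma voom the 4 calls of these falls ended (adjusted p = 0.177, 0.196, 0.145 and 0.128). With DESeq2 they ended too (adjusted p = 0.198, 0.225, 0.181 and 0.180) at log2 changes of -1.77, -1.69, -1.68 and -1.55. Those of MT-ND2, MT-ATP6 and MT-ND1 were -2.56, -2.55 and -2.42 without shPROX1 replicate 3. With 1 library left out, 2 of the 13 genes were called without control replicate 2 or 3, 3 without shPROX1 replicate 2 or 4, 6 without shPROX1 replicate 1, 9 without control replicate 4 and 12 without control replicate 1 or shPROX1 replicate 3. The mitochondrial list was called by camera without control replicate 1 (adjusted p = 3.44e-10), without shPROX1 replicate 3 (adjusted p = 0.0205), with the replicate number as a block (adjusted p = 4.52e-05) and without a filter on low counts (adjusted p = 0.00144). These calls used the preset correlation of 0.01. Over all libraries the estimated correlation of its members was 0.93, at which camera gave adjusted p = 0.646, and fry gave adjusted p = 0.408. Abundant structural RNAs counted 1 higher and 6 lower among 10 measured (1 and 6 adjusted over the list alone). The structural RNA list did not pass (median -0.92, camera adjusted p = 0.238). It was called by camera with the replicate number as a block (adjusted p = 0.00881) and without control replicate 4 (adjusted p = 0.0207). The mitochondrial ribosomal RNAs MT-RNR2 (-4.03 ± 0.69) and MT-RNR1 (-3.14 ± 0.59) and the spliceosomal RNAs RNU5A-1 (-1.57 ± 0.40) and RNU5B-1 (-1.42 ± 0.38) fell. Mitochondrial ribosomal RNA took 0.258% and 0.383% of counts in control replicates 2 and 4, 0.0158% and 0.0192% in control replicates 1 and 3, and 0.00938% to 0.0177% in the shPROX1 libraries (exact two-sided permutation p = 0.0571). Log2 changes of MT-RNR2 and MT-RNR1 were -3.27 and -2.28 without control replicate 4, -3.02 and -2.48 with the replicate number as a block, and -2.78 and -2.27 with limma voom. The signal recognition RNA RN7SL2 (0.04 ± 0.12) did not pass. Small nuclear RNAs took 0.748% of counts in control replicate 1 and 0.236% to 0.404% in the other 7 libraries. The RNU5A-1 and RNU5B-1 calls ended with DESeq2 (adjusted p = 0.0535 and 0.0582), and that of RNU5B-1 also with limma voom (adjusted p = 0.0734). Without control replicate 4, the RN7SL2 log2 change was -0.14 (edgeR adjusted p = 0.0403).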

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

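The tests in this part were chosen after the results they measure had been seen, except the scan of 7-base sequences and its bounds. In 25 of 530 sets of 4 libraries checked (4.72%, where chance gives about 5%) the highest or lowest library stood apart, its gap to the nearest library taking more of the range than Dixon's critical value allows, and 23 of these are given here. For control replicate 1 that share of the range was 0.863 in MYOD1, 0.880 in CCND2, 0.858 in ANLN, 0.841 in KIF20A, 0.842 in the mean of YAP and TAZ targets and 0.928 in the mean of cholesterol genes. It was 0.908 for control replicate 2 in AMOTL1 and 0.834 in NDUFA10. Control replicate 3 stood apart in COL12A1 (0.855), SDC4 (0.934), CCN2 (0.869) and CXCL8 (0.834), and control replicate 4 in the means of S phase genes (0.868) and fibroblast growth factor genes (0.869). Among shPROX1 libraries, replicate 1 stood apart in COL7A1 (0.854) and the sarcomere mean (0.952), replicate 3 in IGF2 (0.921), COL5A2 (0.848), MT-ND4L (0.833) and the ribosomal protein mean (0.932), and replicate 4 in UHRF1 (0.917), GADD45A (0.837) and TAGLN (0.843).

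Genes with a shared 3' UTR sequence were lower after silencing: GCTGGAA was the strongest of all 7-base sequences (t = -12.1 across 10431 genes, which are not independent replicates), and medians ran from -0.11 with AGCTGGAA (708 genes) to 0.01 with GCTGGA alone (1880 genes) and 0.02 with no match (5820 genes). Of 95 searched genes that fell at least 2-fold, 45 carried AGCTGGA or GCTGGAA against 26.5 at matched 3' UTR length (ratio 1.7, permutation p = 1e-04, the smallest that 10000 permutations can give). Both sequences were picked from these same changes and the permutation did not repeat that choice, so this excess is no independent support. The share with GCTGGAA was 1.95 times that of other genes, between the bounds set before the scan was run (2 for the explanation, 1.2 against). Base composition alone is argued against by 387 sequences of the same bases in another order, whose lowest t was -3.28. These shared no 5 bases in a row with AGCTGGAA and its neighbouring bases. Overlapping sequences of the same bases, such as AGCTGGA (t = -9.94) and AAGCTGG (t = -5.40), were left out. AGCTGGA, if left in, would have met the bound for base composition, which was set after the scan. Direct silencing through GCTGGA in the searched 3' UTR cannot apply to the 35 of these 95 genes that lack it there. GCTGGA was read from these same changes and the hairpin sequence is unknown, so other 3' UTR matches were not tested. Sites elsewhere and indirect effects were not tested either, and all of these stay open. Silencing of unintended targets by the hairpin may account for part of the carriers; a cellular microRNA with the same seed stays open, and with 1 hairpin of unknown sequence no effect of its own can be told from loss of PROX1.

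Contractile genes were lower in shPROX1 (median log2 change -0.56 over 38 genes). The list kept its camera call without carriers of a 7-base match (29 genes, adjusted p = 1.25e-06, and adjusted p = 0.0432 with an estimated correlation, against 0.0692 for all 38). Direct silencing through AGCTGGA or GCTGGAA in the searched 3' UTR as the whole cause is argued against by the median of -0.53 without carriers. Other matches to the hairpin were not tested, as its sequence is unknown. GC content and gene length are argued against too, since the median with that offset was -0.56. Uniform dilution by cells without contractile transcripts is argued against by 7 of 24 contractile genes of at least 10 CPM that lay over 3 standard errors above the list median (ACTC1, TNNT1, TNNT2, TPM1, TPM2, DES and MYPN) and 8 that lay as far below. Loss of PROX1 itself and other effects of the hairpin, indirect ones included, stay open, as neither was tested apart from the other.

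Of 13 mitochondrially encoded protein genes 10 were called lower in shPROX1, but their list did not pass (median log2 change -1.12, camera adjusted p = 0.0727). The highest control share of mitochondrial counts was 7.17 times the lowest, more than the 2.86 between the group means, but this rests on control replicate 1: without it the ratios were 1.48 and 3.62. Yield that varies from library to library and a lower level with silencing both stay open. The share gave an exact permutation p = 0.143 over all libraries and an exact p = 0.0286 without control replicate 1. With any other library left out the exact p was 0.143 to 0.257.

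Other divisions of the 8 libraries into 4 and 4 were fitted (35 splits, the real one included). For called genes, chance is argued against: 1 split, the real one, gave 4364, and the highest other gave 12. For genes changed at least 2-fold it is argued against too (1 split as large, 353 against 12). In both cases 1 of 35 is the smallest share that the splits allow, and every other split mixes the groups, so chance is not excluded. For the number of called lists chance is not argued against: 2 splits gave 14 or more, and the highest other gave 15. That split kept 3 of the 4 control libraries together, and the 18 splits with 2 control libraries on each side gave 0 to 5.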

How the results depend on the processing

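The removal of genes (mitochondrial and small structural RNA genes, or carriers of a 7-base match) and the GC and length offset were chosen after seeing the data. Across all alternatives PROX1 stayed lower (log2 change -1.05 to -1.08, -0.99 to -1.15 with 1 library left out), and the count of called genes was 2986 to 4569 in place of 4364 (3788 to 4292 with 1 library left out), except 369 against a 1.5-fold change, which asks for larger changes by construction. DESeq2 called 3247 genes and shared 3211 with edgeR, in the same direction. Removal of carriers left 9639 genes tested and 3090 called, with 3031 of 3196 earlier calls kept. Genes changed at least 2-fold numbered 538 without a filter on low counts in place of 353 and 281 to 473 otherwise (366 to 404 with 1 library left out). Called lists numbered 14, with an estimated correlation 1, with fry 25 and without a filter 22. With 1 library left out they numbered 12 to 15. The run without a filter also tested lists too small for the main comparison, and its 22 includes calls of those. Among the 39 lists of the main comparison, 7 gained a call in that run and 32 were unchanged. Without carriers 12 of the 14 stayed and the stemness (adjusted p = 0.0195) and immediate early lists (adjusted p = 0.0134) were gained. The slow minus fast shift of 0.185 was 0.220 with at least 1 CPM in 4 libraries and 0.0773 to 0.223 with 1 library left out. Of 223 named genes besides PROX1, 198 kept their side of the threshold in all alternatives run, as did 9 of 39 lists. None of these reversed direction with a call in either fit, and sign changes without a call were not counted. RN7SL2 (0.04) took the opposite sign with a call without control replicate 4 (-0.14; -0.14 to 0.13 with 1 library left out). The cause of these changes was not tested. In the simulated data 63.8% of log2 changes of 0.5 were recovered, and smaller changes were missed more often than larger ones. Far fewer genes were changed there than were called here, which makes the adjusted threshold harder to pass. The share of changes missed in these libraries was therefore not measured, and small ones can be missed.

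With the replicate number as a replicate block, 4187 genes were called, 358 of them at least 2-fold, with 17 lists, a PROX1 log2 change of -1.07 and a slow minus fast shift of 0.185 (exact sign-flip p = 0.125, the smallest that 16 arrangements allow). The numbers did not pair the libraries: deviations of same-numbered libraries correlated at -0.03, -0.05, 0.05 and -0.03 across genes, and 1 of 8 libraries correlated best with its own number.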

Other observations

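Groupings, genes and tests in this part were chosen after the data were seen. Long non-coding transcripts also differed between the groups. Of 604 tested, 121 (20%) were called, 54 higher and 67 lower, against 36.7% of 11403 protein-coding genes; whether the shares differ at equal expression was not tested. MIR222HG, the host transcript of microRNAs 221 and 222 (chromosome X, 45745211 to 45770274), rose from 4.02 ± 1.54 CPM in control to 15.6 ± 2.68 CPM in shPROX1 (log2 change 1.96 ± 0.21), and SFTA1P (3.38 ± 0.883 to 13.2 ± 1.22 CPM, log2 change 1.96 ± 0.19), GASAL1 (4.43 ± 1.33 to 9.50 ± 2.42 CPM, log2 change 1.11 ± 0.23) and SBF2-AS1 (10.9 ± 1.91 to 21.4 ± 2.80 CPM, log2 change 0.98 ± 0.14) rose as well. HAGLR in the HOXD cluster (chromosome 2, 176173195 to 176188958) fell from 11 ± 0.465 to 3.95 ± 0.245 CPM (-1.47 ± 0.18). IGF2-AS fell (-1.41 ± 0.15) like IGF2, whose annotated span it overlaps on the opposite strand. Exon overlap was not computed for the non-coding genes of this part, so shared reads may enter their counts. DNM3OS (84.0 ± 3.91 to 42.3 ± 2.88 CPM) and the small nucleolar RNA host SNHG29 (603 ± 35.2 to 311 ± 21.9 CPM) fell too.

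Protein-coding families defined by a shared symbol root with at least 8 tested members gave 173 sets. Camera called 0 of them, 17 had an unadjusted p under 0.05 and 0 were called with an estimated correlation. The proteasome subunits named PSMD came closest (8 of 14 members higher and 0 lower, median log2 change 0.17, camera adjusted p = 0.0660).

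The annotated PROX1 transcript of 8498 bases held AGCTGGA at 2 coding sites and no GCTGGAA. The site in exon 2 read AGCTGGAG (chromosome 1, 213997260 to 213997266 for AGCTGGA) and that in exon 5 AGCTGGAT (chromosome 1, 214035767 to 214035773). Genes with AGCTGGAT in the 3' UTR (383) had a median log2 change of -0.10 and those with AGCTGGAG (734) of -0.05. The reverse complement of GCTGGAA, TTCCAGC (1935 genes), had a median of -0.01. Among 134 searched genes that rose at least 2-fold, 33 (24.6%) carried AGCTGGA or GCTGGAA, against 26.0% of the other genes.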
